A study of Mus musculus with 27 samples.

How the data were processed

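RNA from whole hearts of 14-day-old CD-1 mice was sequenced in 27 libraries, 3 hearts in each of 9 groups. Mothers of the PTU groups received 0.15% propylthiouracil, which blocks thyroid hormone synthesis, in iodine-deficient chow from embryonic day 13.5. Pups were injected under the skin every day from postnatal day 1 with saline, with phenoxybenzamine (PHE, 10 ug per g per day), which blocks alpha-adrenergic receptors, or with propranolol (PRO, 20 ug per g per day), which blocks beta-adrenergic receptors. The labels put the libraries in 2 sets. Set A holds 5 groups: saline, PHE, PHE+PRO, PTU+PHE and PTU+PHE+PRO. Set B holds 4 groups: saline, PRO, PTU and PTU+PRO. Every PHE group is therefore in set A, and PTU alone and PRO alone are in set B.

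The authors extracted RNA with Trizol from frozen hearts, made libraries with the TruSeq RNA kit, trimmed reads with cutadapt, aligned them to the mouse genome mm10 with STAR and counted them per gene with featureCounts. The deposited table holds counts, that is, raw whole-number reads per gene, with no normalisation by the authors. The annotation release, the strand setting and the handling of reads that map to several places are not stated. The table has 51826 genes, of which 51633 identifiers matched a symbol in the reference annotation, 193 did not, and 71 symbols stand for more than 1 identifier. No read was counted in any library for 13440 genes. Totals ran from 30791885 to 78913915 assigned reads per library. A count of 0 allows up to 3 reads in a library of that depth. These limits cover counting error only, since reads without molecular identifiers are not independent molecules. In the header 2 columns share the name of PHE+PRO heart 2, and they are called PHE+PRO 2a and 2b here, without a replicate number. Sex was read from Xist and Y-linked genes.

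Genes with too few reads were removed with filterByExpr of edgeR by group (minimum count 10, minimum total 15), which left 19119 genes. Counts were scaled by TMM, and 1 quasi-likelihood model with 9 group means was fitted with robust dispersion in edgeR 4.0.16 (R 4.3.3), with 18 residual degrees of freedom and a prior count of 0.125. From it came 18 comparisons: each treated group against the saline group of its set, PTU or PRO added to another treatment, the interactions of PTU and PRO within each set, differences between effects of the 2 sets, and saline against saline. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of that comparison, two-sided. The standard error of a log2 fold change is its size divided by the square root of its F statistic, and n is 3 hearts per group throughout. PTU was given to the mothers and the litter of each heart is not known. Hearts of 1 group may therefore not be independent, and litter cannot be told apart from PTU. Similarity of effects between backgrounds is given as a correlation across genes, which are not independent replicates, and PTU against saline was chosen there so that no library enters both sides.

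Before the data were examined, 48 gene lists were fixed. They cover thyroid hormone targets of the heart, fetal and adult sarcomere, adrenergic and cyclic AMP signalling, calcium handling and ion channels, cell cycle, mitochondrial and other metabolism, stress and signalling pathways, and markers of the cell types a heart sample could hold. All 48 had at least 4 tested members. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, with adjustment over the lists. Camera compares a list with all other genes. The count of called members is given over all genes tested and again adjusted over the list alone. Across the 18 comparisons 304 list calls were made at the preset correlation, and 40 of these held with an estimated correlation.

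Genes named in the text were picked by a rule that was also set at that point. Against saline, they had an adjusted p under 0.05, a mean of at least 5 counts per 1e6 reads (CPM) and values in the 3 treated hearts that did not overlap those of the 3 saline hearts, which chance gives in 10% of genes. From these came the 10 largest rises and the 10 largest falls. Other comparisons gave 5 of each, and those of 4 groups had no overlap criterion. Gene models without a proper name were counted, not named. Up to 4 members with the smallest p were added from each called list, as was any member of the thyroid hormone, fetal sarcomere and adrenergic lists. A few genes that the rule picked are not reported here. Values of processed pseudogenes are uncertain because their reads can come from the parent gene.

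The alternatives were RLE factors, no filter, DESeq2 1.42.0, fits of 1 set or only of the groups compared, replicate number as a block, sex as a covariate, leaving out each library in turn, the estimated correlation for lists, and genes over 10 CPM for the comparison of backgrounds. After the data had been seen these were added: an offset for transcript length per library, leaving out the 3 libraries with the steepest length trend, saline paired across sets, leaving out saline 1 of both sets, and the effect of PRO in 4 backgrounds. The length trend used 10711 genes with a log2 CPM of at least 2, and the measure given per library is the median log2 CPM of genes over 8 kb minus that of genes under 1 kb. Single named genes were tested with RLE factors, DESeq2, the replicate block, the length offset and libraries left out, and not without the filter, with sex or in the smaller fits. The replicate block was not run where PHE+PRO takes part, because of the shared column name.

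The method was tested on simulated data. In a simulation of PTU against saline with 18581 genes, the model found 49.3% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 98.5% of those changed 4-fold, and 4.97% of its calls were false. When a length trend like that of the PHE libraries was simulated together with 200 changed genes, 1319 unchanged genes were called, against 8 with the length offset. The offset found 34.3% of the genes changed 1.5-fold, against 61.2% without it. In the simulation without a trend, 11.1% of the calls of DESeq2 were false. None of 47 unchanged lists was called. The simulated genes were drawn independently of each other, so this does not test list calls where genes are correlated. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.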

Results

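Gene expression was measured by RNA sequencing in 27 libraries of whole hearts of CD-1 mice at postnatal day 14, 3 in each of 9 groups. Whether the saline hearts of the 2 sets are different animals is open. The groups combine block of thyroid hormone synthesis (PTU, propylthiouracil), alpha-adrenergic block (PHE, phenoxybenzamine) and beta-adrenergic block (PRO, propranolol) with a saline group in each of 2 sets. In set A the libraries held 49868973 to 58907822 assigned reads for saline, 46862777 to 78913915 for PHE, 42017505 to 52747151 for PHE+PRO, 52065876 to 71796054 for PTU+PHE and 30791885 to 62134596 for PTU+PHE+PRO. In set B they held 47896044 to 58206987 for saline, 54034563 to 60840542 for PRO, 44683064 to 60792630 for PTU and 57565906 to 68609024 for PTU+PRO. Both sexes occur in every group except PHE, whose 3 hearts were male by their Y-linked genes. In both sets saline hearts 1 and 2 were male and saline heart 3 was female. Mitochondrial genes took 12.0% to 19.7% of the reads of a library.

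The main axis of variation parted hearts with PTU from hearts without it. Over 11069 genes, the leading component held 48.2% of the variance and the next 26.5%, along which every library of set A lay below every library of set B. Most of the comparisons therefore stay within a set, where treated and saline hearts were sequenced under the same label.

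**Figure D1:**
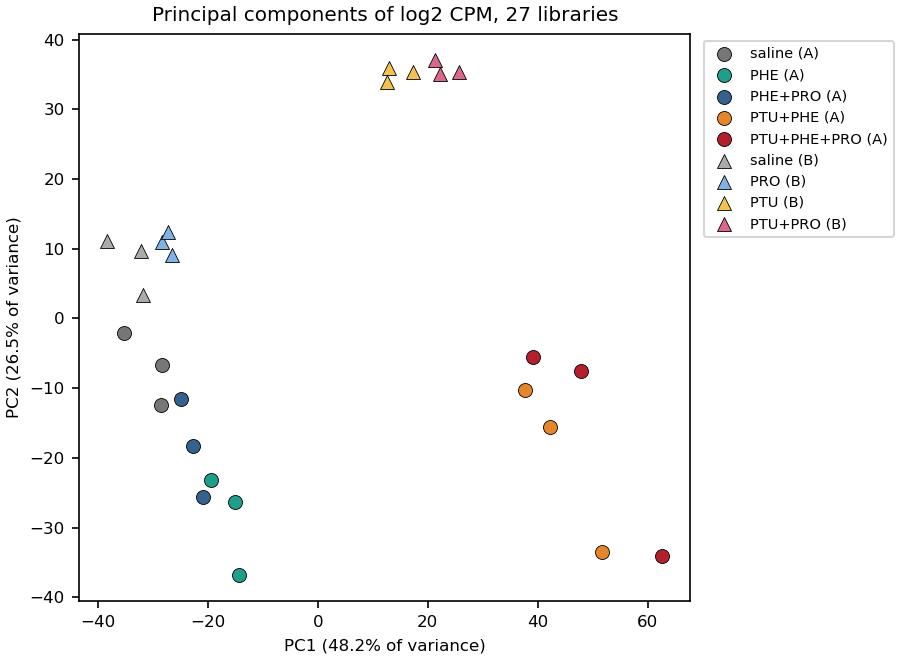
Principal components of log2 CPM for the 27 libraries, circles for set A and triangles for set B, with PC1 (48.2% of the variance) on the horizontal and PC2 (26.5%) on the vertical axis. Hearts with PTU lie at the right and hearts without it at the left, and PTU groups of the 2 sets lie apart along PC2.

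PTU was compared with saline in set B. No hormone level is in the data, so effects of hormone loss cannot be told apart from those of the chow or of the drug itself. Of 10 fetal sarcomere genes 7 rose and 2 fell. Tnni1 (ENSMUSG00000026418, mm10 chromosome 1, 135779434 to 135810989), the slow troponin I that the fetal heart uses, rose 151-fold (log2 7.23 ± 0.40 SE, n = 3 hearts per group, adjusted p = 9.9e-12). Myh7 (ENSMUSG00000053093, chromosome 14, 54970684 to 54994626), the slow beta myosin heavy chain, rose by 3.58 ± 0.15 on the log2 scale (adjusted p = 1.6e-14). Its neighbour Myh6 (ENSMUSG00000040752, 54941921 to 54966927), the fast alpha myosin heavy chain of the adult mouse heart, fell by 3.39 ± 0.17 (adjusted p = 4.1e-13). Other steep rises were those of Grik3, a kainate receptor subunit (5.06 ± 0.39), Tubb2b, a beta tubulin (3.94 ± 0.20), Krt18, a simple epithelial keratin (3.85 ± 0.31), Bex1 (3.75 ± 0.37) and Rxfp1, the relaxin receptor (3.69 ± 0.41). The steepest falls were those of Pnpla3, a lipid droplet acylhydrolase (-6.53 ± 0.35), Art1, a muscle ADP-ribosyltransferase (-6.47 ± 0.29), Tuba8, an alpha tubulin (-6.40 ± 0.37), Klhl33 (-5.93 ± 0.41) and Scn4b, a sodium channel beta subunit (-5.67 ± 0.41). In all, 2735 genes rose and 2880 fell, 5615 of 19119 tested, and 1963 of these changed at least 2-fold. A fit of set B alone called 8340 genes. Of the 20 genes picked by the rule, 19 kept their call in each alternative run for single genes and with each library left out.

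**Figure D2:**
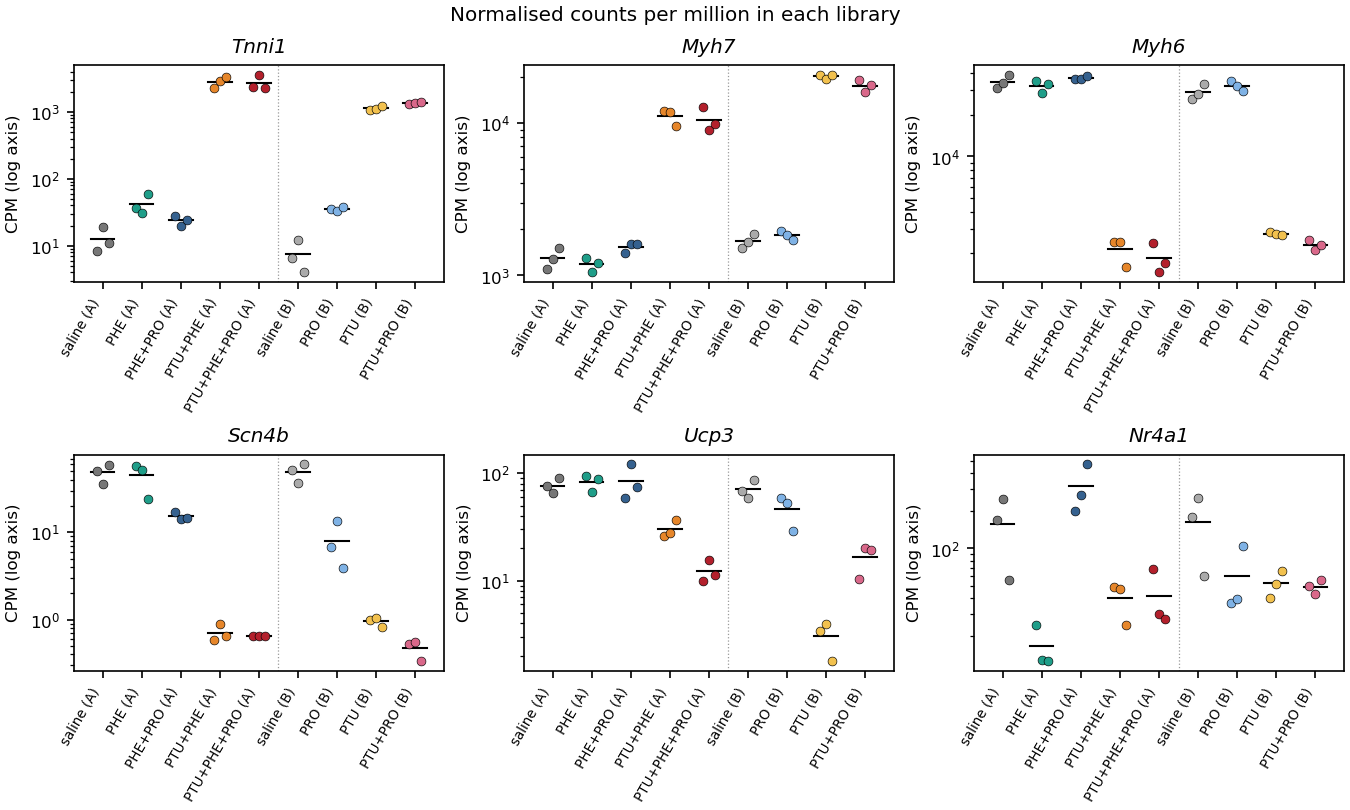
Normalised CPM on a log axis for 6 genes in each library, with a bar at the group mean and a dotted line between set A and set B. Tnni1 and Myh7 were high and Myh6 and Scn4b low in the 4 groups with PTU, and Nr4a1 was lowest in the PHE group.

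Among genes that thyroid hormone induces in the heart, 11 of 14 fell and 1 rose after PTU, or 12 and 1 adjusted over the list alone. The list median was -1.85 (camera adjusted p = 5e-25, and 0.00019 with an estimated correlation). Hcn2, a pacemaker channel, fell by 4.42 ± 0.16, Atp2a2, the calcium pump of the sarcoplasmic reticulum, by 2.27 ± 0.14 and Hr, a corepressor gene of the hormone receptor, by 3.73 ± 0.25, while Ppargc1a rose by 0.44 ± 0.16. Of 7 genes that the hormone represses, 5 rose, and adjusted over the list alone 5 rose and 1 fell (camera adjusted p = 2.4e-06, and 0.016 with an estimated correlation). Of 10 fetal sarcomere genes 7 rose and 2 fell, with the same counts adjusted over the list alone (median 1.11, camera adjusted p = 1.2e-07, and 0.0016 with an estimated correlation). The 2 that fell were Acta1, skeletal alpha actin (-4.39 ± 0.46), and Acta2, smooth muscle actin (-1.06 ± 0.20). Of 8 ventricular markers 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 7.1e-12, and 3.2e-05 with an estimated correlation), led after Myh7 by the transcription factors Hey2 (2.99 ± 0.14) and Irx5 (1.66 ± 0.15). Imprinted genes of fetal growth rose in 8 of 13 cases and fell in 1, or 9 and 1 adjusted over the list alone (median 0.88, camera adjusted p = 4.2e-09, and 0.0016 with an estimated correlation), among them H19 (1.91 ± 0.12) and the growth factor Igf2 (1.22 ± 0.09).

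Genes of energy metabolism fell after PTU. Of 44 nuclear genes of oxidative phosphorylation 40 fell and none rose, or 43 adjusted over the list alone (median -0.60, camera adjusted p = 1.8e-13, and 0.36 with an estimated correlation). Uqcrc1, of complex III, fell by 0.84 ± 0.10 and Cox7a1, the muscle form of a complex IV subunit, by 1.51 ± 0.18. Of 20 citric acid cycle genes 18 fell and 1 rose, or 19 and 1 adjusted over the list alone (camera adjusted p = 5.9e-10, and 0.21 with an estimated correlation). Of 30 genes of fatty acid oxidation 21 fell and 1 rose, or 22 and 2 adjusted over the list alone (camera adjusted p = 4.2e-09, and 0.21 with an estimated correlation), including Cpt2 (-1.41 ± 0.11) and Pdk4, which restrains glucose oxidation (-2.84 ± 0.36). All 13 protein genes of the mitochondrial genome fell, also adjusted over the list alone (median -0.68, camera adjusted p = 1e-05, and 0.21 with an estimated correlation), and 8 did with the length offset. Markers of macrophages fell in 14 of 15 cases, also adjusted over the list alone (median -1.15, camera adjusted p = 5.9e-10, and 0.029 with an estimated correlation), among them Mrc1 (-1.21 ± 0.12), Csf1r (-0.98 ± 0.11) and Lyz2 (-1.24 ± 0.15). Of 36 genes of the G2 and M phases 3 rose and 1 fell, or 2 and 1 adjusted over the list alone (median 0.42, camera adjusted p = 0.028, and 0.79 with an estimated correlation). The median became 0.15 without saline 3, and the 3 became 0 without saline 3 and 10 without saline 1, 6 with DESeq2, 9 with sex in the model, 7 in a fit of set B alone and 8 with the length offset. In all, 24 of the 48 lists were called after PTU, 6 of them also with an estimated correlation.

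**Figure D3:**
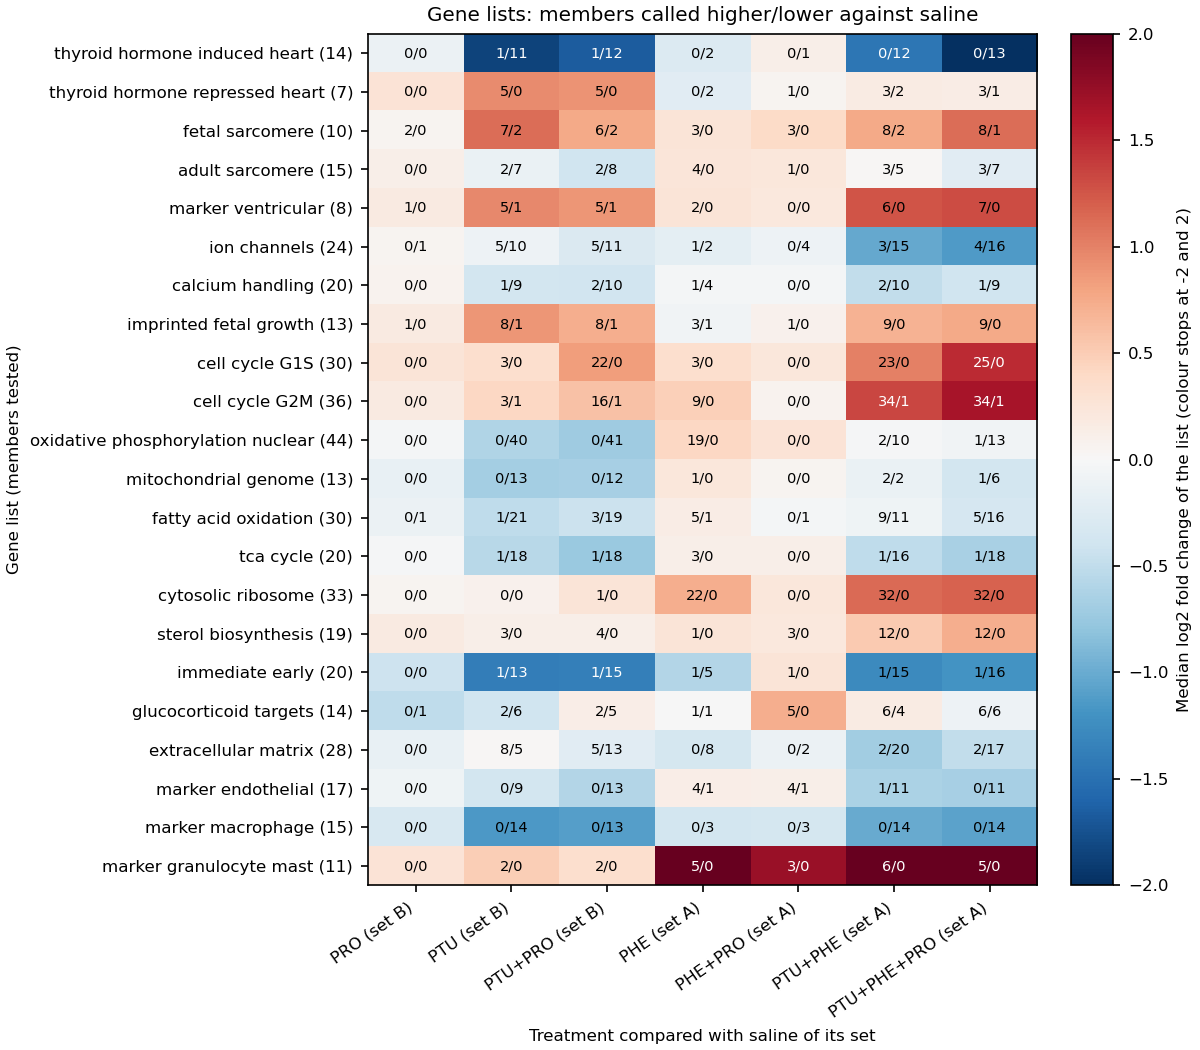
Gene lists fixed beforehand (vertical axis, number of members tested in brackets) for each treatment against the saline group of its set (horizontal axis), coloured by the median log2 fold change. Each cell gives the members called higher and lower, for example 1 and 11 of 14 thyroid hormone induced genes after PTU.

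PTU with propranolol, against saline of set B, raised fetal sarcomere genes, and cell cycle genes were among those that rose. Of 10 fetal sarcomere genes 6 rose and 2 fell, also adjusted over the list alone (median 0.76, camera adjusted p = 0.00027, and 0.029 with an estimated correlation). Tnni1 rose 179-fold (log2 7.49 ± 0.40, adjusted p = 5.1e-12), Grik3 by 6.52 ± 0.40 and Dlk1, an imprinted fetal growth regulator, by 4.35 ± 0.63. Bmp7, a growth factor, rose by 3.55 ± 0.20 and Ptgds, prostaglandin D synthase, by 3.57 ± 0.29. Tuba8 fell by 7.96 ± 0.41, Lrtm1 by 7.67 ± 0.68, Scn4b by 6.71 ± 0.44 and Acta1 by 5.36 ± 0.48. Of the 14 thyroid hormone induced genes 12 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 4.1e-19, and 0.0013 with an estimated correlation). Of 44 oxidative phosphorylation genes 41 fell, or 44 adjusted over the list alone (median -0.71, camera adjusted p = 3.3e-14, and 0.33 with an estimated correlation). Of 30 genes of the G1 and S phases 22 rose, or 23 adjusted over the list alone (median 0.84, camera adjusted p = 4.5e-07, and 0.42 with an estimated correlation), with Tk1, thymidine kinase, at 1.82 ± 0.15 and the replication helicase gene Mcm7 at 1.04 ± 0.14. The 22 became 14 without PTU+PRO 2. Of 36 G2 and M genes 16 rose and 1 fell, or 18 and 1 adjusted over the list alone (camera adjusted p = 0.0036, and 0.68 with an estimated correlation), and the 16 became 4 without saline 3, 25 with sex in the model and 9 in a fit of these groups. Endothelial markers fell in 13 of 17 cases, or 14 adjusted over the list alone (median -0.58, camera adjusted p = 5.4e-06, and 0.15 with an estimated correlation), for example the receptor genes Tie1 (-0.93 ± 0.10) and Aplnr (-1.34 ± 0.15). The test called 6857 genes, 3388 higher and 3469 lower.

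PTU with phenoxybenzamine, against saline of set A, raised fetal sarcomere genes and nearly all mitotic genes measured. Of 10 fetal sarcomere genes 8 rose and 2 fell, also adjusted over the list alone (median 0.76, camera adjusted p = 0.00067, and 0.031 with an estimated correlation). Tnni1 rose 225-fold (log2 7.81 ± 0.41, adjusted p = 2.7e-12), Krt18 by 5.10 ± 0.32 and Bex1 by 4.81 ± 0.38. The neutrophil protein genes S100a8 and S100a9 rose by 4.52 ± 0.58 and 3.98 ± 0.52. Art1 fell by 7.42 ± 0.31, Pnpla3 by 7.08 ± 0.36 and Itgb6, an integrin subunit, by 6.29 ± 0.27. Of 36 G2 and M genes 34 rose and 1 fell, also adjusted over the list alone (median 1.33, camera adjusted p = 4.1e-11, and 0.47 with an estimated correlation). Cdc20, which activates the anaphase promoting complex, rose by 2.01 ± 0.21, the ubiquitin enzyme gene Ube2c by 2.82 ± 0.30 and cyclin B2 (Ccnb2) by 2.34 ± 0.26. Of 30 G1 and S genes 23 rose, also adjusted over the list alone (camera adjusted p = 1.2e-06, and 0.49 with an estimated correlation). Of 33 cytosolic ribosome genes 32 rose, also adjusted over the list alone (median 1.13, camera adjusted p = 1.3e-07, and 0.56 with an estimated correlation). Their median was 0.67 with the offset for transcript length, a measure in which PHE libraries stand apart.

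In the same PTU+PHE hearts 12 of 14 thyroid hormone induced genes fell, also adjusted over the list alone (median -1.45, camera adjusted p = 1.5e-16, and 0.0032 with an estimated correlation), with Hcn2 at -4.70 ± 0.17 and Myh6 at -4.01 ± 0.18. Ion channel genes fell in 15 of 24 cases and rose in 3, or 16 and 3 adjusted over the list alone (median -1.03, camera adjusted p = 6.2e-08, and 0.019 with an estimated correlation). The potassium channel gene Kcnd2 fell by 4.59 ± 0.31. Of 15 macrophage markers 14 fell, also adjusted over the list alone (median -1.01, camera adjusted p = 4e-07, and 0.092 with an estimated correlation). Of 28 extracellular matrix genes 20 fell and 2 rose, or 21 and 2 adjusted over the list alone (median -0.69, camera adjusted p = 3.6e-06, and 0.49 with an estimated correlation), among them Col8a1 (-2.33 ± 0.22) and Lama2, a laminin chain of the muscle basement membrane (-1.41 ± 0.13). Sterol synthesis genes rose in 12 of 19 cases, also adjusted over the list alone (camera adjusted p = 0.0097, and 0.49 with an estimated correlation), led by lanosterol synthase, Lss (1.71 ± 0.12). The test called 10214 genes, 5398 higher and 4816 lower.

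PTU with both blockers, against saline of set A, changed 10458 genes, of which 5491 rose and 4967 fell. In a fit of set A alone the count was 8808, and 8399 for PTU+PHE. In a fit of set B alone it was 8340 for PTU and 9370 for PTU+PRO. The order of these counts against saline therefore depends on the fit. Tnni1 rose 217-fold (log2 7.76 ± 0.40, adjusted p = 2.2e-12), Grik3 by 5.76 ± 0.39, Nkd2, an inhibitor of Wnt signalling, by 4.81 ± 0.26 and Cited1, a transcriptional cofactor, by 4.53 ± 0.30. Tuba8 fell by 7.98 ± 0.43, Itgb6 by 7.52 ± 0.31 and Scn4b by 6.23 ± 0.44. Of 36 G2 and M genes 34 rose and 1 fell, also adjusted over the list alone (median 1.65, camera adjusted p = 8.2e-13, and 0.35 with an estimated correlation), including the mitotic kinase Cdk1 (2.40 ± 0.25) and the cytokinesis gene Racgap1 (2.11 ± 0.22). Of 30 G1 and S genes 25 rose, or 26 adjusted over the list alone (median 1.49, camera adjusted p = 5.5e-12, and 0.35 with an estimated correlation), such as Tk1 (1.93 ± 0.15) and the licensing factor Cdt1 (2.48 ± 0.25). Of 14 thyroid hormone induced genes 13 fell, also adjusted over the list alone (median -2.17, camera adjusted p = 1.1e-18, and 0.00055 with an estimated correlation). Ventricular markers rose in 7 of 8 cases, also adjusted over the list alone (camera adjusted p = 4.1e-08, and 0.00055 with an estimated correlation). Fetal sarcomere genes rose in 8 of 10 cases and fell in 1, also adjusted over the list alone (median 1.11, camera adjusted p = 1.5e-05, and 0.0073 with an estimated correlation). Ion channel genes fell in 16 of 24 cases and rose in 4, also adjusted over the list alone (median -1.14, camera adjusted p = 4.9e-08, and 0.0073 with an estimated correlation). Ribosome genes rose in 32 of 33 cases, also adjusted over the list alone (median 1.18, camera adjusted p = 9.2e-08, and 0.55 with an estimated correlation), and their median was 0.84 with the length offset. All 20 genes picked by the rule kept their call in each alternative run for single genes and with each library left out.

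**Figure D4:**
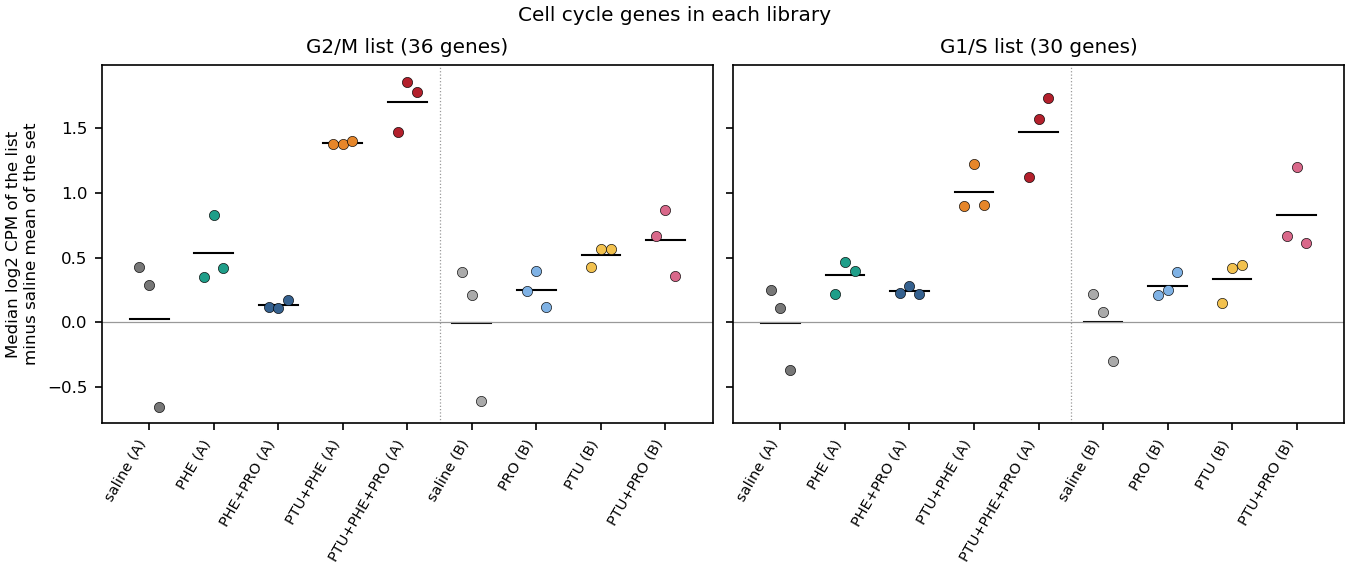
Median log2 CPM of the 36 G2 and M genes (left) and the 30 G1 and S genes (right) in each library, minus the saline mean of its set, with a bar at the group mean and a dotted line between the sets. For G2 and M genes, PTU+PHE libraries lie between 1.38 and 1.40 and libraries with PTU and both blockers between 1.47 and 1.86, above every other library; saline 3 is low in both sets (-0.65 and -0.61).

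Phenoxybenzamine alone, against saline of set A, lowered Nr4a1 and raised the neutrophil genes S100a8 and S100a9. Of the 48 lists 15 were called, none of them with an estimated correlation. Nr4a1 (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795), an orphan receptor induced by cyclic AMP, fell by 3.24 ± 0.62 (adjusted p = 0.0061). Hipk2, a nuclear kinase, fell by 2.24 ± 0.36 and Tnfrsf25, a death receptor, by 1.99 ± 0.28. S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721) rose by 2.85 ± 0.50 (adjusted p = 0.0033), Txnip, an inhibitor of thioredoxin, by 1.92 ± 0.37, Tnni1 by 1.74 ± 0.32 and Klf10, a transcription factor, by 1.27 ± 0.17. Granulocyte markers rose in 5 of 11 cases, or 6 adjusted over the list alone (median 2.32, camera adjusted p = 0.0052, and 0.43 with an estimated correlation), with S100a8 at 2.83 ± 0.56 and Retnlg at 2.76 ± 0.57. Of 15 cyclic AMP response genes 3 fell, or 5 adjusted over the list alone (median -0.73, camera adjusted p = 9e-05, and 0.43 with an estimated correlation). Of 15 macrophage markers 3 fell, or 5 adjusted over the list alone (camera adjusted p = 0.0012, and 0.47 with an estimated correlation), among them the mannose receptor Mrc1 (-0.89 ± 0.12) and Adgre1 (-1.16 ± 0.19).

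The test called 2827 genes after PHE, 1557 higher and 1270 lower. In PHE libraries short transcripts were high relative to long ones: the median of transcripts over 8 kb minus that of transcripts under 1 kb averaged -0.38 over the 12 libraries with PHE and 0.44 in saline of set A. Of 33 ribosome genes 22 rose, or 31 adjusted over the list alone (median 0.73, camera adjusted p = 8.2e-13, and 0.65 with an estimated correlation), but 1 did with the length offset (median 0.32). Of 44 oxidative phosphorylation genes 19 rose, or 39 adjusted over the list alone (median 0.41, camera adjusted p = 5.2e-11, and 0.65 with an estimated correlation), and 1 did with the offset (median 0.07). Of 28 matrix genes 8 fell, or 12 adjusted over the list alone (camera adjusted p = 1.7e-05, and 0.65 with an estimated correlation), and 1 did with the offset. Of 36 G2 and M genes 9 rose, or 10 adjusted over the list alone (median 0.48, camera adjusted p = 2.3e-07, and 0.65 with an estimated correlation), 5 did with the offset, 5 without the 3 steepest libraries, 4 in a fit of these groups, 0 in a fit of set A alone and 0 without saline 3. The median of these genes was 0.48 with the offset too and 0.15 without saline 3. In a simulation of such a length trend 1319 unchanged genes were called. The 2827 became 1021 with the offset, 1513 with a replicate block and 78 in a fit of set A alone. It was 1799, 911 and 640 without saline 1, 2 and 3, and 1481 and 396 without PHE 2 and 3. Of the 20 genes picked by the rule, 12 kept their call in each alternative run for single genes, those named here among them. These alternatives did not include the fit of set A alone, a fit of these groups or a model with sex. All 3 PHE hearts were male and saline 3 was female.

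**Figure D5:**
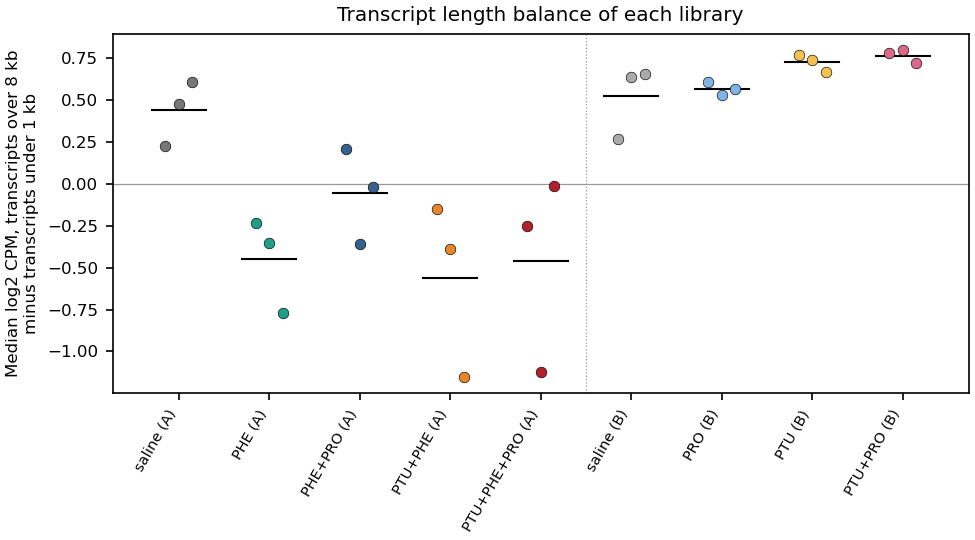
Median log2 CPM of transcripts over 8 kb minus that of transcripts under 1 kb in each library, with a bar at the group mean and a dotted line between set A and set B. The 12 libraries with PHE lie between -1.15 and 0.21, and the other 15 between 0.23 and 0.80.

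Both blockers together, PHE+PRO against saline of set A, raised the glucocorticoid response genes Fkbp5 and Cdkn1a. Fkbp5, a cochaperone of the glucocorticoid receptor, rose by 1.74 ± 0.25 (adjusted p = 0.00062), Cdkn1a, the cell cycle inhibitor p21, by 1.52 ± 0.24, Tent5b, a poly(A) polymerase, by 1.97 ± 0.38 and Rbp7, a retinol binding protein, by 1.47 ± 0.25. Prune2 fell by 2.21 ± 0.25 (adjusted p = 5.8e-05), Myl1, a skeletal myosin light chain, by 1.99 ± 0.25, Scn4b by 1.66 ± 0.33 and Sox4, a developmental transcription factor, by 1.47 ± 0.26. Of 14 glucocorticoid targets 5 rose, or 6 adjusted over the list alone (median 0.72, camera adjusted p = 2.1e-05, and 0.18 with an estimated correlation). Fetal sarcomere genes rose in 3 of 10 cases, or 5 adjusted over the list alone (camera adjusted p = 0.0087, and 0.18 with an estimated correlation), with Acta2 at 1.03 ± 0.20. Endothelial markers rose in 4 of 17 cases and fell in 1, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.023, and 0.49 with an estimated correlation), with endoglin (Eng) at 0.69 ± 0.13. Of 15 macrophage markers 3 fell, or 5 adjusted over the list alone (camera adjusted p = 0.023, and 0.49 with an estimated correlation), with the fractalkine receptor Cx3cr1 at -1.18 ± 0.22. The test called 1069 genes, 479 higher and 590 lower, against 1758 with DESeq2, 163 in a fit of set A alone and 404 in a fit of these groups only. It called 487, 601 and 373 without saline 1, 2 and 3, and 252 without PHE+PRO 2a.

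Propranolol alone, against saline of set B, changed few genes, among them Scn4b, Mme, Tnni1 and Acta2. Scn4b (ENSMUSG00000046480, chromosome 9, 45138395 to 45154152) fell by 2.63 ± 0.34 (adjusted p = 0.00054), Mme, the membrane protease neprilysin, by 1.82 ± 0.17 (adjusted p = 3.2e-06) and Prune2 by 1.75 ± 0.25. Tnni1 rose by 2.23 ± 0.32 (adjusted p = 0.002), Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590) by 1.28 ± 0.20 and Ncam1, a cell adhesion molecule, by 0.70 ± 0.09. Of 8 ventricular markers 1 rose, or 3 adjusted over the list alone (median 0.18, camera adjusted p = 2.1e-05, and 0.0038 with an estimated correlation). That 1 was Irx5 (0.75 ± 0.15), whose call was lost without saline 1, 2 or 3 (adjusted p = 0.095, 0.074 and 0.11) and without PRO 2 or 3 (adjusted p = 0.075 and 0.092). Of 10 fetal sarcomere genes 2 rose, also adjusted over the list alone (camera adjusted p = 0.0088, and 0.19 with an estimated correlation). Glucocorticoid targets had a median of -0.51, and 1 of 14 fell, or 4 adjusted over the list alone (camera adjusted p = 2.1e-05, and 0.12 with an estimated correlation). The test called 52 genes, 32 higher and 20 lower, against 118 without the filter, 203 with DESeq2, 104 with sex in the model, 406 in a fit of set B alone, 94 in a fit of these groups and 96 with the length offset. It called 17, 29 and 21 without saline 1, 2 and 3, and 28, 23 and 19 without PRO 1, 2 and 3.

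The effect of PTU was also measured within hearts that had a blocker. Tnni1 rose under PHE by 6.07 ± 0.37, under PHE+PRO by 6.84 ± 0.39 and under PRO by 5.26 ± 0.36, and Grik3 by 5.72 ± 0.41, 5.17 ± 0.38 and 5.51 ± 0.37. Tuba8 fell by 7.28 ± 0.39, 8.36 ± 0.43 and 8.28 ± 0.42. Thyroid hormone induced genes fell in 11, 13 and 10 of 14 cases, or 12, 13 and 11 adjusted over the list alone, where 1 also rose under PRO. Their camera adjusted p was 1.6e-19, 2.4e-23 and 1.9e-19, and 0.0012, 0.00019 and 0.0012 with an estimated correlation. Of 36 G2 and M genes 27 rose and 1 fell under PHE, or 32 and 1 adjusted over the list alone (camera adjusted p = 3.6e-07, and 0.56 with an estimated correlation). The 27 became 18 without PHE 1 and 16 without the 3 steepest libraries. Under PHE+PRO 35 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 3.1e-14, and 0.27 with an estimated correlation). Under PRO 6 rose and 1 fell, or 3 and 1 adjusted over the list alone (median 0.44, camera adjusted p = 0.078, and 0.86 with an estimated correlation). The 6 became 1 without PRO 1, 3 with a replicate block and 15 in a fit of these groups. Of 44 oxidative phosphorylation genes 41 fell under PRO, or 44 adjusted over the list alone (camera adjusted p = 5.4e-15, and 0.31 with an estimated correlation). Genes of mitochondrial biogenesis and uncoupling fell under PHE+PRO in 9 of 16 cases and rose in 2, also adjusted over the list alone (camera adjusted p = 0.0012, and 0.025 with an estimated correlation), led by the muscle regulator Perm1 (-1.61 ± 0.11) and the lipid oxidation regulator Ppara (-1.89 ± 0.20).

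PTU changed 7038 genes under PHE (3489 higher, 3549 lower), 8987 under PHE+PRO (4724 and 4263) and 5771 under PRO (2870 and 2901). In fits of these groups only the counts were 5067, 5043 and 8089, and in fits of 1 set 5210, 7217 and 8425, so their order depends on the fit. Across all 19119 genes, the PTU effect alone and under PRO had a Pearson r of 0.79 (Spearman 0.76), alone and under PHE 0.65 (0.58), and alone and under PHE+PRO 0.61 (0.52). The r between PRO and PHE was 0.69 (0.64), between PRO and PHE+PRO 0.65 (0.57), and between PHE and PHE+PRO 0.76 (0.75). These are correlations across genes, which are not independent replicates. The r of 0.79 and 0.76 are from pairs within a set, and the lower values are from pairs that cross the sets. Set and PHE therefore cannot be told apart in these values. PTU raised 1194 genes and lowered 1497 in all 4 backgrounds. Alone and under PRO, 1990 genes were higher in both, where 410.6 would be by chance, and 2182 lower, where 437 would be. The effect of PRO was compared in the same way over saline, PTU, PHE and PTU+PHE as backgrounds. Its Pearson r lay between 0.01 and 0.20, or 0.05 and 0.32 with genes over 10 CPM, and PRO raised 1 gene and lowered 1 in all 4. Over PHE and PTU+PHE, 49 genes were higher in both, where 9 would be by chance. There 24 were lower in both, where 7.1 would be, and 7 were called in opposite directions.

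With propranolol added to phenoxybenzamine, Nr4a1 and Sik1, which fell after PHE, were higher than in PHE hearts. The fall of Sik1 after PHE was no longer called without saline 2 (adjusted p = 0.058). Both comparisons hold the same 3 PHE hearts, and against saline Nr4a1 did not pass in PHE+PRO hearts (0.99 ± 0.57, adjusted p = 0.32). Against PHE, Nr4a1 rose by 4.22 ± 0.65 (adjusted p = 0.0011), its relative Nr4a2 by 3.69 ± 0.69 (adjusted p = 0.0036) and the salt-inducible kinase Sik1 by 2.91 ± 0.44 (adjusted p = 0.00087). Prune2 fell by 2.18 ± 0.25 (adjusted p = 4e-05), Txnip by 2.05 ± 0.37 and Rasl11b by 1.66 ± 0.23. Of 15 cyclic AMP response genes 7 rose, or 12 adjusted over the list alone (median 1.56, camera adjusted p = 2.1e-13, and 0.057 with an estimated correlation). Of 14 glucocorticoid targets 6 rose and 1 fell, or 9 and 1 adjusted over the list alone (median 0.87, camera adjusted p = 2.4e-07, and 0.057 with an estimated correlation), with Cdkn1a at 2.05 ± 0.25 and Fkbp5 at 1.32 ± 0.25. The test called 1112 genes, 593 higher and 519 lower, against 1724 with DESeq2 and 232 in a fit of set A alone. It called 556, 538 and 499 without PHE 1, 2 and 3, and 638 and 735 without PHE+PRO 1 and 2a.

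Propranolol added to PTU with phenoxybenzamine raised Acta2 by 1.48 ± 0.20 (adjusted p = 0.00058), the transcription factor gene Arid5a by 1.53 ± 0.28 and Prkag3, a subunit of the energy sensor AMPK, by 1.35 ± 0.23. Syt7, a calcium sensor of vesicle fusion, fell by 1.47 ± 0.19 (adjusted p = 0.00029) and Tceal7 by 1.58 ± 0.31. Fatty acid oxidation genes fell in 4 of 30 cases, or fell in 6 and rose in 1 adjusted over the list alone (camera adjusted p = 1.1e-07, and 0.45 with an estimated correlation), with Acad11 at -0.54 ± 0.10. None of the 30 G1 and S genes passed in edgeR over all genes, where 20 had an unadjusted p under 0.05 and higher values, and 6 passed in DESeq2, 2 without the filter, 2 with the length offset, 1 with RLE factors and 6 without PTU+PHE+PRO 1. By contrast, 7 rose adjusted over the list alone (median 0.48, camera adjusted p = 6.6e-11, and 0.51 with an estimated correlation). The test called 549 genes, 289 higher and 260 lower, against 1131 with DESeq2, 293 with a replicate block, 70 in a fit of set A alone and 3 in a fit of these groups. It called 229 and 283 without PTU+PHE 2 and 3, and 917, 1041 and 286 without PTU+PHE+PRO 1, 2 and 3.

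Propranolol added to PTU in set B raised Ucp3 (ENSMUSG00000032942, chromosome 7, 100472990 to 100486432), a mitochondrial carrier of muscle, by 2.45 ± 0.34 (adjusted p = 0.00075). Xirp2, an actin-binding repeat protein of muscle, fell by 1.76 ± 0.24 (adjusted p = 0.00052). These were the 2 of 10 genes picked by the rule that kept their call in each alternative run for single genes. Extracellular matrix genes fell in 3 of 28 cases, or 9 adjusted over the list alone (median -0.31, camera adjusted p = 1.2e-14, and 0.33 with an estimated correlation). None of 30 G1 and S genes passed in edgeR over all genes, where 21 had an unadjusted p under 0.05 and higher values. In DESeq2 2 passed, and in edgeR 9 with sex in the model, 3 in a fit of set B alone, 2 without the filter and 2 in a fit of these groups. By contrast, 16 rose adjusted over the list alone (median 0.53, camera adjusted p = 4e-16, and 0.33 with an estimated correlation), and the median was 0.30 without PTU+PRO 2. The test called 123 genes, 55 higher and 68 lower, against 202 without the filter, 316 with DESeq2, 724 in a fit of set B alone, 1028 in a fit of these groups and 186 with the length offset. It called 35, 68 and 62 without PTU 1, 2 and 3, and 40 and 44 without PTU+PRO 2 and 3.

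Whether propranolol acts differently with and without PTU was tested as an interaction. In set B it called 3 genes, 2 higher and 1 lower. The interaction was 3.04 ± 0.46 for Ucp3 (adjusted p = 0.01), which fell by 4.54 ± 0.37 after PTU, and 1.04 ± 0.16 for Rsrp1, a splicing-related gene (adjusted p = 0.0087). The remaining one, Gm9855 (-5.09 ± 0.61), had a mean of 2.52 CPM, lies outside the rule and was chosen after its value was seen. Without saline 3 the calls of Ucp3 and Rsrp1 were lost and 1 gene was called, and without saline 2 there were 6. That of Rsrp1 was also lost without PRO 2, without PRO 3 and with a replicate block (adjusted p = 0.058, 0.057 and 0.052). The count was 26 without the filter, 45 with DESeq2, 7 with sex in the model, 94 in a fit of set B alone or of these groups, and 8 with the length offset. Of 10 fetal sarcomere genes none passed in edgeR over all genes, 3 had an unadjusted p under 0.05, 1 passed in DESeq2, and 2 had lower interaction values adjusted over the list alone (median -0.42, camera adjusted p = 1.3e-06, and 0.0085 with an estimated correlation). Of 14 glucocorticoid targets none passed in edgeR, 5 had an unadjusted p under 0.05, 3 passed in DESeq2, and 5 had higher values adjusted over the list alone (median 0.59, camera adjusted p = 4.3e-09, and 0.01 with an estimated correlation).

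Under PHE in set A the same interaction called 200 genes, 90 higher and 110 lower. It was 2.42 ± 0.39 for Ankrd1, a stress-responsive sarcomere protein (adjusted p = 0.0038), 2.40 ± 0.35 for Prune2 and 2.23 ± 0.32 for Rasl11b. It was -2.38 ± 0.45 for Fam222a, -2.33 ± 0.42 for Apold1, an endothelial early response gene, and -2.15 ± 0.34 for Cdkn1a. Cyclic AMP response genes had lower values in 3 of 15 cases, or 9 adjusted over the list alone (median -1.08, camera adjusted p = 5.4e-12, and 0.056 with an estimated correlation). Glucocorticoid targets did in 2 of 14, or 9 with 1 higher adjusted over the list alone (median -1.07, camera adjusted p = 4.1e-09, and 0.043 with an estimated correlation). The count was 580 with DESeq2, 11 in a fit of set A alone, 9 in a fit of these groups and 311 with the length offset. It was 85, 74 and 116 without PHE 1, 2 and 3, 93 without PHE+PRO 2a, 69, 83 and 453 without PTU+PHE 1, 2 and 3, and 633 and 130 without PTU+PHE+PRO 1 and 2.

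Comparisons across the sets are made between effects, each taken within its own set. This removes a set difference only where it is additive. PTU alone was only in set B and the PHE groups only in set A. A response to PTU that differed between the sets therefore cannot be told apart from an effect of the blockers. The effect of PTU with both blockers exceeded that of PTU alone in cell cycle genes. Of 36 G2 and M genes 25 were higher and none lower, or 32 adjusted over the list alone (median 1.16, camera adjusted p = 1.7e-14, and 0.58 with an estimated correlation), for example Cenpa, the centromeric histone (1.08 ± 0.16), and Cdk1 (2.07 ± 0.34). The 25 became 11 without saline 1 of set B, 14 in a fit of these groups, 15 without the 3 steepest libraries and 34 with a replicate block and saline paired across sets. The median was 1.17, 1.06 and 1.16 in the last 3, and lay between 0.87 and 1.43 with 1 library left out. Of 30 G1 and S genes 22 were higher, or 24 adjusted over the list alone (median 1.12, camera adjusted p = 1.4e-12, and 0.58 with an estimated correlation). Matrix genes were lower in 17 of 28 cases, or 21 adjusted over the list alone (median -0.62, camera adjusted p = 2.9e-10, and 0.58 with an estimated correlation). Ribosome genes were higher in 29 of 33 cases, or 32 adjusted over the list alone (camera adjusted p = 6.6e-12, and 0.58 with an estimated correlation), and in 18 with the length offset. Angptl4, an inhibitor of lipoprotein lipase, was higher by 2.90 ± 0.66 (adjusted p = 0.0051), and Itgb6 (-3.29 ± 0.39, adjusted p = 4.9e-05), Hipk2 (-2.78 ± 0.50) and Nt5c1a, an AMP nucleotidase (-2.67 ± 0.45), were lower. In all 4636 genes differed, 2413 higher and 2223 lower, against 2940 without PTU+PHE+PRO 2 and 2636 without saline 1 of both sets.

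The effect of PTU under both blockers also differed from its effect alone, with the same limit on what a comparison across sets can tell. Angptl4 was higher by 3.50 ± 0.67 (adjusted p = 0.0031) and the acyl-CoA thioesterase Acot1 by 3.01 ± 0.44, while Fam222a (-3.11 ± 0.45), Adamtsl2 (-2.57 ± 0.34) and Itgb6 (-2.56 ± 0.40) were lower. G2 and M genes were higher in 24 of 36 cases, or 33 adjusted over the list alone (median 1.19, camera adjusted p = 1.3e-15, and 0.46 with an estimated correlation), and the 24 became 10 without saline 1 of set B, 14 in a fit of these groups and 13 without the 3 steepest libraries, with medians of 0.98, 1.20 and 1.09. G1 and S genes were higher in 14 of 30 cases, or 19 adjusted over the list alone (median 0.86, camera adjusted p = 2.4e-09, and 0.46 with an estimated correlation), and the 14 became 5 without saline 1 of set B, 9 without the filter, 9 in a fit of these groups and 8 without the 3 steepest libraries. In all 2842 genes differed, 1337 higher and 1505 lower, against 1256 in a fit of these groups. Without PTU+PHE+PRO 1 and 2 there were 4490 and 1875, without saline 1 of set B 1626 and without PTU 1 1805.

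The saline groups of the 2 sets differed in 814 genes, 536 higher and 278 lower in set B. The fit took the saline hearts of the 2 sets as different animals. Whether they are is open, since hearts with the same number deviated alike from their group means. The correlations of these deviations across genes were 0.84, 0.83 and 0.89 for saline 1, 2 and 3. If the hearts are the same, the 814 genes come from a fit that left out their pairing. Gnas (ENSMUSG00000027523), the stimulatory G protein subunit, was 21.2-fold higher in set B (log2 4.41 ± 0.25, adjusted p = 8.2e-11), and Adnp, a homeobox gene, was higher by 3.81 ± 0.29 and Cebpb, a transcription factor, by 3.16 ± 0.29. Sumo2 (-1.20 ± 0.13) and Ppia, cyclophilin A (-1.14 ± 0.17), were lower. Of 11 adipocyte markers 5 were lower in set B, also adjusted over the list alone (camera adjusted p = 9.9e-08, and 0.12 with an estimated correlation). Ribosome genes were lower in 4 of 33 cases, or 10 adjusted over the list alone (camera adjusted p = 3.8e-09, and 0.75 with an estimated correlation). The count was 354 without saline 1 of both sets and 516 without saline 1 of set A. Set and PHE cannot be told apart in any direct comparison of a PHE group with a group of set B, and the comparisons across sets were therefore made between effects taken within a set. That step removes only an additive set difference.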

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

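The tests of transcript length, of replicate number and the smaller-step test of saline hearts were chosen after the values were seen, as were the length and cell type tests of cell cycle genes and the splits of 2 groups.

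A test of the difference between groups picked out these results. The interaction of PTU and PRO in set B called 3 genes, with Ucp3 at 3.04 and Rsrp1 at 1.04. Under PHE it called 200 genes, with Ankrd1 at 2.42, Prune2 at 2.40, Rasl11b at 2.23, Ccn2 at 2.15, Rrm2 at 1.87, Nr4a1 at -4.17, Sik1 at -2.81, Fam222a at -2.38, Gem at -2.37 and Apold1 at -2.33. Between the effect of PTU under PHE+PRO and its effect alone 2842 genes differed, with Angptl4 at 3.50, Lars2 at 3.20, Mir6236 at 3.04, Acot1 at 3.01, Fam222a at -3.11, Olfr1372-ps1 at -2.89, Nr4a2 at -2.86, Adamtsl2 at -2.57 and Itgb6 at -2.56. Many of these calls depend on the fit or on 1 library. Of genes picked by the rule, 0 of 2 in set B, 5 of 10 under PHE and 6 of 10 across sets kept theirs throughout.

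Long transcripts were low relative to short ones in PHE hearts (mean -0.38, against 0.44 in saline of set A). Against a shift shared by all libraries of set A as a cause, saline namesakes of the 2 sets differed by at most 0.16. That value cannot address the harvest, extraction or library preparation of the treated hearts of set A. Every one of them had PHE, and the saline hearts may be the same in both sets. A batch of the treated hearts therefore remains open. Preparation or RNA quality of single hearts also remains open, as the measure had a pooled SD of 0.44 within PHE groups and 0.14 within the others. Alpha block also remains open: all 12 PHE libraries lay below every other library, but the closest were 0.21 and 0.23. No value measured here separates these explanations.

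Saline hearts with the same number in the 2 sets were alike. A day or order tied to the number in all groups was argued against by a median correlation of -0.13 over 33 other same-numbered pairs, 9 of them over 0.1. For pairs of a heart with PTU and a heart without it, this test cannot address a shared litter, since their mothers differed. Pairs alike in PTU could share a litter, but no median was taken over those pairs alone. The test also cannot address a litter, day or order shared only by the saline hearts. Sex was argued against, since the difference between the male hearts 1 and 2 had r = 0.8 between sets, over genes that are not independent replicates. That the same hearts were sequenced in both sets was open in the test set beforehand, with the same order in 60% of 5 genes and at most 40% for other numberings. In the test chosen afterwards, with steps of 0.3 log2, 92.8% of 153 genes kept the order and at most 3.92% did under other numberings, which is in line with the same hearts and is a hypothesis found and tested in the same data.

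The effect of PTU with both blockers on cell cycle genes exceeded that of PTU alone. PTU alone was only in set B and the PHE groups only in set A. A response to PTU that differed between the sets therefore cannot be told apart from an effect of the blockers. Transcript length was argued against, since the G2 and M median was 1.20 with the length offset. Single libraries may account for part of the count, since 11 genes were called without saline 1 of set B and 33 without saline 3 of set B, but the median lay between 0.87 and 1.43 with any library left out, against 1.16. More cells of a non-muscle type remain open, since the granulocyte markers had a median of 0.94 and the adipocyte markers of 0.61. Macrophage markers had a median of -0.09 and fibroblast markers of -0.43.

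Libraries were also split into groups without regard to treatment. For comparisons of 2 groups, 10 splits, the real grouping among them, are too few for a share under 0.05. Every other split puts hearts of both real groups on each side. A real difference then adds to the spread within the groups and lowers the calls. The low counts of other splits therefore do not show what hearts without an effect would give. Against saline, the real grouping gave 2827 genes for PHE, 1069 for PHE+PRO, 10214 for PTU+PHE, 10458 for PTU with both blockers, 52 for PRO, 5615 for PTU and 6857 for PTU+PRO, and the highest other split gave 0 each time. It gave 814 and 0 for saline against saline, and 7038 and 1, 8987 and 362, and 5771 and 0 for PTU added to PHE, PHE+PRO and PRO. For PRO added to PHE and to PTU it gave 1112 and 2, and 123 and 6. For PRO added to PTU+PHE, 4 of 10 splits, the real grouping included, gave at least the real 549 genes. The highest gave 3159. It put PTU+PHE 2 and 3 and PTU+PHE+PRO 2 together, with length measures of -0.39, -1.15 and -1.12.

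For comparisons of 4 groups 100 splits were made. As many genes as with the real grouping came from 10 for the interaction in set B (3 against a highest of 3868) and from 19 for the interaction under PHE (200 against 6830). They came from 6 for PTU with both blockers minus PTU alone (4636 against 6791), and from 3 for the PTU effect under PHE+PRO minus that alone (2842 against 5471). Splits that mix PTU hearts unevenly can carry the PTU effect itself, which was not tested.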

How the results depend on the processing

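The offset for length, leaving out the steepest libraries, saline pairing and leaving out saline 1 of both sets were chosen after seeing the data. Of 1207 named values, 1205 kept their direction and call with RLE factors and 1205 with DESeq2, 834 of 888 with a replicate block, 1139 of 1207 with the length offset and 697 of 747 without the 3 steepest libraries. Leaving out 1 library ended the call of 252 of the 1207 values at least once, where a value is a gene in 1 comparison. Saline pairing kept 107 of 108, and leaving out saline 1 of both sets 83 of 108. Akap6 after PHE (-0.40 ± 0.13, adjusted p = 0.041) reversed to 0.04 with the length offset. The replicate block was not run for comparisons with PHE+PRO, since 2 columns share a name. Fits of 1 set lowered the count of every comparison within set A and raised that of every comparison within set B. PHE then called 78 genes and PRO 406, against 2827 and 52 in the main fit of both sets. The spread between 2 hearts of a group, as chi-square per degree of freedom, was 26.894 to 155.741 in set A. In set B it was at most 39.075. This goes with the direction of the moves, but whether it caused them was not tested. The cause of other moves was not tested. Depth limits genes with few reads most, as the shallowest library holds 30791885 reads.

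PHE against saline called 2827 genes, and 1513 with the block, 78 in a fit of set A alone and 1021 with the length offset. PHE+PRO called 1069, and 1758 with DESeq2, 163 in a fit of set A alone and 404 in a fit of these groups. PRO called 52, and 118 without the filter, 203 with DESeq2, 104 with sex, 406 in a fit of set B alone, 94 in a fit of these groups and 96 with the offset. PTU added to PHE+PRO called 8987, and 5043 in a fit of these groups. PRO added to PHE called 1112, and 1724 with DESeq2 and 232 in a fit of set A alone. PRO added to PTU+PHE called 549, and 1131 with DESeq2, 293 with the block, 70 in a fit of set A alone and 3 in a fit of these groups. PRO added to PTU called 123, and 202 without the filter, 316 with DESeq2, 724 in a fit of set B alone, 1028 in a fit of these groups and 186 with the offset. The interaction in set B called 3, and 26 without the filter, 45 with DESeq2, 7 with sex, 94 in a fit of set B alone, 94 in a fit of these groups and 8 with the offset. Under PHE it called 200, and 580 with DESeq2, 11 in a fit of set A alone, 9 in a fit of these groups and 311 with the offset. The PTU effect under PHE+PRO minus that alone called 2842, and 1256 in a fit of these groups. Without saline 1 of both sets, PTU with both blockers minus PTU called 2636 and saline against saline 354. Of 304 list calls 40 held with an estimated correlation. With genes over 10 CPM, r of PTU effects rose to 0.91 for alone and PRO, 0.77 for alone and PHE, 0.74 for alone and PHE+PRO, 0.80 for PRO and PHE, 0.75 for PRO and PHE+PRO, and 0.85 for PHE and PHE+PRO.

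With 1 library left out, counts ranged from 396 to 2052 for PHE, 252 to 1241 for PHE+PRO, 8843 to 10023 for PTU+PHE, 9150 to 10633 for PTU with both blockers, 17 to 29 for PRO, 4348 to 4750 for PTU and 5476 to 5888 for PTU+PRO. For PTU added to PHE, PHE+PRO and PRO they were 5726 to 6789, 7804 to 9325 and 4501 to 4821. For PRO added to PHE, PTU+PHE and PTU they were 499 to 743, 229 to 1041 and 35 to 109. The interactions gave 1 to 6 and 69 to 633, the differences across sets 1626 to 4490 and 2940 to 5838, and saline against saline 516 to 668. The r ranged from 0.76 to 0.79, 0.60 to 0.66, 0.55 to 0.62, 0.64 to 0.69, 0.60 to 0.65 and 0.71 to 0.75, in the order above.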

Other observations

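Of the adipocyte genes, 5 were present at low levels in every library of set A and nearly absent from set B. Ucp1, the uncoupling protein of brown fat, lay between 0.905 and 10.8 CPM in set A and at 0.0441 CPM or less in set B. Adipoq lay between 0.118 and 1.42 CPM in set A, Cidec between 0.168 and 1.61, Plin1 between 0.157 and 1.76 and Cfd between 0.0479 and 1.68, each highest in PHE+PRO 2a. In set B they reached at most 0.0554, 0.0147, 0.0882 and 0.0185 CPM. Other genes of the list, such as Fabp4 and Lipe, did not pass between the saline groups (adjusted p = 0.65 and 0.98).

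The T cell genes Cd8a, Cd8b1 and Lck were highest in saline 1 of both sets, at 1.38, 0.804 and 2.16 CPM in set A and 1.37, 0.741 and 1.98 in set B. Got2-ps1, a processed pseudogene, was at 20.8, 0.827 and 0.745 CPM in saline 1, 2 and 3 of set A and at 12.5, 1.02 and 0.771 in set B. Y-linked genes were at 75.7 CPM in PTU+PRO 2 and at 122 to 191 CPM in the other male hearts. Xist was at 2.59 CPM in the male saline 1 of set A and at 1.53 in the male PTU+PHE+PRO 3.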
